A study of Homo sapiens with 13 samples.

How the data were processed

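Messenger RNA of AC16 cells was sequenced in 13 libraries of 4 groups: 3 control, 3 FCCP, 4 preconditioning and 3 preconditioning+FCCP libraries. Groups were taken from the treatment given in the labels. Per the labels' protocols, RNA was extracted with a column kit for fibrous tissue, mRNA was selected with poly-T beads and fragmented, and cDNA was primed with random hexamers. The labels describe both a directional and a non-directional second strand without saying which was used, and the strand setting of the counting is not given in the sources used here, so reads of a gene and of an overlapping antisense gene may not have been told apart.

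The deposited values are raw read counts per gene. HISAT2, HTSeq and the human build hg19 are named in the submitters' processing notes, without versions. Each deposited table held counts for 63241 Ensembl gene IDs, and 5013 of these IDs are absent from GENCODE 29, so the annotation release was not settled and no coordinates are given. Symbols were found for 42338 IDs. The rows that name no gene were left out of library sizes and tests: reads outside genes made up 2.13% to 5.20% of all reads in a library, reads that overlapped several genes 11.0% to 12.4%, and reads aligned to several places 3.16% to 11.5%. Genes that overlap others or share sequence with copies, such as ribosomal protein genes with their pseudogenes and mitochondrial genes with nuclear copies, therefore have less certain levels.

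Library sizes were 14970803 to 20636229 gene counts. Genes were kept with the default expression filter of edgeR, which left 16756 genes. Counts were scaled with TMM factors and compared with edgeR's quasi-likelihood test (version 4.0.16, R 4.3.3) in a single fit of all 13 libraries with a term per group, and p-values were adjusted with the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. Adjusted p-values of genes are from this test unless another is named. Fold changes are log2 values with a standard error (SE), taken as the absolute log2 change divided by the square root of the test's F, and levels are CPM, the share of a gene in the counts of its library after scaling. The contrasts were FCCP against control, preconditioning against control, preconditioning+FCCP against FCCP, preconditioning+FCCP against preconditioning, and the interaction, which is the FCCP effect with preconditioning minus the FCCP effect without it.

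Before the data were examined, 47 gene lists with 935 members, the contrasts, the tests, the alternatives and the rule for named genes were fixed. The rule takes, per comparison, the 6 called genes with the largest rise and the 6 with the largest fall among genes of at least 5 mean CPM in a compared group whose libraries do not overlap (no overlap rule for the interaction), up to 4 called members per described list with the smallest adjusted p, or 2 values where no member was called, and 12 fixed stress and mitochondrial genes. Lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 47 lists, and again with a correlation estimated per list. The share of counts from mitochondrial genes was compared with an exact two-sided permutation test, adjusted over 4 comparisons.

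The functions were tested on simulated counts with 200 changed genes among 16756. Fewer genes were changed than the real comparisons called, so the p-value needed for a call was lower in the simulations. For FCCP against control, 20% of genes changed 2-fold and 70% of genes changed 4-fold were recovered. For preconditioning against control these shares were 34% and 73%, for preconditioning+FCCP against FCCP 27% and 69%, for preconditioning+FCCP against preconditioning 27% and 84%, and for the interaction 3% and 57%.

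Alternatives were DESeq2 size factors, library totals alone, mitochondrial genes left out, other filters, DESeq2 (1.42.0), limma-voom, the compared groups alone, a replicate block, stricter thresholds and each library left out in turn. After the data were seen, 4 more were added: control 3, FCCP 1 and preconditioning+FCCP 3 left out together, a term for the library set described in the results, fits within each set, and a smooth trend on gene length and GC content taken out of each library, for which 96.5% of tested genes had values.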

Results

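AC16 is a human cell line made by fusing adult ventricular heart muscle cells with a transformed fibroblast line. FCCP is a protonophore that collapses the mitochondrial membrane potential. The series title and design text describe optogenetic preconditioning of mitochondria with a construct named mOpto, followed or not by FCCP. The labels give the genotype of all 13 libraries as wildtype, and do not say whether control and FCCP cells carried the construct or received light. There were 3 control, 3 FCCP, 4 preconditioning and 3 preconditioning+FCCP libraries, with 14970803 to 20636229 gene counts each. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No pair of libraries within a group agreed within sampling noise, and the lowest chi-square per degree of freedom was 3.32.

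The libraries were parted into 2 sets at the largest gap in the share of reads aligned to several places, between 5.22% and 7.13%. This share ranged from 3.16% to 5.22% in the lower set and from 7.13% to 11.5% in the higher. The sets divided the control and preconditioning+FCCP groups, while the FCCP libraries all lay in the higher and the preconditioning libraries all in the lower. The share of reads aligned to several places was above 6.17% in control 1, control 2, FCCP 1 to 3 and preconditioning+FCCP 3, called the higher-share set (6 libraries). It was below this value in control 3, preconditioning 1 to 4 and preconditioning+FCCP 1 and 2, called the lower-share set (7 libraries). The first principal component held 31.5% of the variance and the second, which followed these sets, 30.6%. Control 3 correlated best with preconditioning 2 (r = 0.967 across genes, which are not independent replicates), and FCCP 1 with preconditioning+FCCP 3 (r = 0.965). Of 26 cardiomyocyte markers 12 were expressed enough to be tested, against 14 of 15 fibroblast, 10 of 10 smooth muscle, 9 of 12 endothelial and 4 of 13 immune cell markers.

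**Figure D1:**
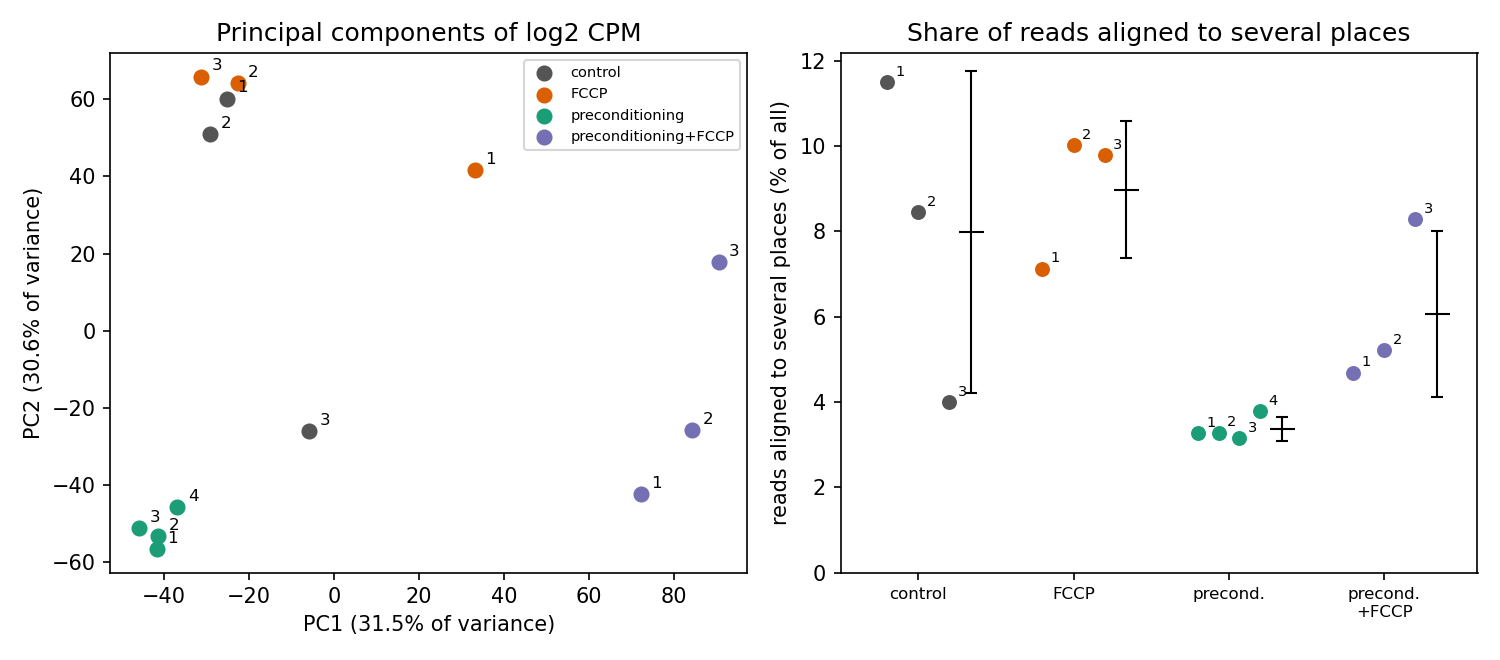
The left panel plots each library by its first and second principal component of log2 CPM, which hold 31.5% and 30.6% of the variance, and the right panel plots the share of reads aligned to several places in percent, with numbers naming replicates and bars giving the group mean ± SD. Control 3 lies at 4.00% beside the preconditioning libraries, and preconditioning+FCCP 3 at 8.28% beside the control and FCCP libraries.

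The first comparison asked what FCCP did to cells without preconditioning. Genes of cholesterol synthesis rose in 12 of 20 cases (17 adjusted over the list alone), with a median log2 change of 1.28 (camera adjusted p = 3.95e-14, and p = 0.543 with an estimated correlation). Among them were MVD (1.69 ± 0.28), MVK (1.61 ± 0.30) and IDI1 (1.49 ± 0.28) of the mevalonate pathway and DHCR7 (1.96 ± 0.38) of the last steps. The list mean was 5.85 log2 CPM in FCCP 1 and 6.61 and 7.08 in FCCP 2 and 3, against 5.26 to 5.51 in control. Of 12 fatty acid synthesis genes 4 rose (7 adjusted over the list alone), among them the fatty acid synthase FASN (1.81 ± 0.44) and the desaturase FADS2 (2.05 ± 0.44), with camera adjusted p = 6.18e-05, and p = 0.719 with an estimated correlation. Among targets of TGF-beta and YAP, 3 of 18 fell (6 adjusted over the list alone), which were the coagulation initiator F3 (−1.92 ± 0.29), CCN2 (−1.45 ± 0.29) and ANKRD1 (−3.48 ± 0.78), with camera adjusted p = 0.0139, and p = 0.719 with an estimated correlation. The list calls of TGF-beta and YAP targets ended without FCCP 2 and without control 3.

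The 6 largest rises were FOSB (3.32 ± 0.72), RASD1 (3.29 ± 0.43), RND1 (3.11 ± 0.53), RGS2 (2.59 ± 0.38), RAMP1 (2.57 ± 0.34) and H2BC21 (2.41 ± 0.43). The 6 largest falls were the hyaluronan synthase HAS2 (−4.07 ± 0.85), ESM1 (−3.86 ± 0.86), MIR34AHG (−3.82 ± 0.67, with 16 counts in all FCCP libraries together), KRTAP2-3 (−3.62 ± 0.84), the mitochondrial tRNA gene MT-TP (−3.48 ± 0.66) and ANKRD1 (−3.48 ± 0.78). HAS2 stood at 8.54, 5.53 and 69.7 CPM in control 1, 2 and 3. Of the stress genes fixed beforehand, the transcription factor ATF3 rose (2.27 ± 0.49) and GDF15 fell (−1.94 ± 0.39). DDIT3 (0.82 ± 0.44), CHAC1 (0.05 ± 0.96), ASNS (1.11 ± 1.00), HMOX1 (−1.29 ± 0.46), HSPD1 (−0.34 ± 0.34), LONP1 (−0.17 ± 0.19), PPARGC1A (0.41 ± 0.48), TXNIP (−0.35 ± 0.50), SQSTM1 (−0.80 ± 0.44) and TRIB3 (−0.07 ± 0.57) did not pass. The FCCP libraries differed in these genes: CHAC1 was at 135.7 CPM in FCCP 1 and at 1.38 and 4.56 CPM in FCCP 2 and 3, and DDIT3, the stress factor CHOP, at 71.5, 18.04 and 13.2 CPM. Without FCCP 1, CHAC1 was called lower (−3.97).

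In all, 590 of 16756 genes were called by edgeR, 268 higher and 322 lower. The count was 17 with the compared groups alone, 1078 without a filter, 1326 by DESeq2 and 382 by limma-voom. With library totals as the only scaling, 58.0% of 395 calls were higher, against 45.4%. By camera, 12 of 47 lists passed, none of them with an estimated correlation. The lists not yet described that passed had estimated-correlation adjusted p = 0.719, or 0.543 for the clock. They were mitochondrially encoded mRNAs (median −1.02, none of 13 called, camera adjusted p = 0.00505, MT-ND6 at −2.33 ± 0.70), cytosolic ribosomal proteins (median 0.33, none of 40 called, camera adjusted p = 1.27e-06, RPS3 at 0.68 ± 0.20), complex I (NDUFS4 higher, 0.78 ± 0.20), complexes II to IV (UQCRC1 higher, 0.60 ± 0.16), lysosomal genes (CTSA higher, 0.80 ± 0.15), NF-kB cytokines (CCL2 lower, −3.39 ± 0.77), snoRNA hosts (SNHG7 1.26 ± 0.29 and SNHG5 1.83 ± 0.49 higher), the clock (PER2 −1.11 ± 0.26 and NR1D2 −0.79 ± 0.20 lower) and histones (H2BC21 higher).

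Within the higher-share set (3 FCCP and 2 control libraries) edgeR called 31 genes and the cholesterol median was 1.36 with 0 members called, and the lower-share set held no FCCP library. The count was 337 without control 1, 328 without control 2, 893 without FCCP 1, 142 without FCCP 2, 185 without FCCP 3 and 3113 without control 3, FCCP 1 and preconditioning+FCCP 3. Of 32 called genes taken by the rule, 11 held their call without each library in turn: RASD1, RND1, RGS2, RAMP1, H2BC21, MIR34AHG, CTSA, MVD, MVK, F3 and CCN2. Calls ended for 17 genes without FCCP 2 and for 17 without FCCP 3, HAS2, ESM1, KRTAP2-3, ANKRD1, MT-TP, GDF15, FASN and FADS2 in either case, and IDI1 and DHCR7 without FCCP 3. They ended for 12 genes without control 1, among them FOSB, ATF3, FASN and FADS2, for 9 without control 2, for 5 without control 3, ESM1, KRTAP2-3 and ANKRD1 among them, and for 4 without FCCP 1, ATF3 and SNHG7 among them. The list calls of cholesterol synthesis, fatty acid synthesis, lysosomal genes and ribosomal proteins were the 4 that held without each library. With the library set as a term the list calls of ribosomal proteins, complex I, complexes II to IV, NF-kB cytokines, TGF-beta and YAP targets, snoRNA hosts and histones ended.

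The next comparison asked what preconditioning did on its own. Cholesterol synthesis genes rose in 19 of 20 cases (19 adjusted over the list alone), with a median log2 change of 1.82 (camera adjusted p = 5.32e-16, and p = 0.364 with an estimated correlation). HMGCS1 (3.52 ± 0.43) and LSS (1.87 ± 0.25) were among them. HMGCS1 was at 27.8 to 46.9 CPM in control and at 230.4 to 483.3 CPM in preconditioning libraries. All 12 fatty acid synthesis genes rose (12 adjusted over the list alone), with ACLY (1.13 ± 0.17), ACACA (1.42 ± 0.22), FADS1 (1.75 ± 0.27) and ACSL3 (2.01 ± 0.22) as examples (camera adjusted p = 2.93e-10, and p = 0.364 with an estimated correlation). Among the largest rises were INSIG1 (3.67 ± 0.62), HMGCS1, LRIG1 (3.24 ± 0.45), the desaturase SCD (3.14 ± 0.63) and FADS2 (2.79 ± 0.44).

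Genes of the respiratory chain and of the ribosome were lower. Of 37 complex I subunits 23 fell (25 adjusted over the list alone), with a median of −0.70 and NDUFB1 at −1.92 ± 0.31 (camera adjusted p = 1.16e-08, and p = 0.677 with an estimated correlation). Of 23 subunits of complexes II to IV 14 fell (15 lower and 1 higher adjusted over the list alone), COX6A1 among them (−2.15 ± 0.35), and of 16 ATP synthase subunits 11 (12 adjusted over the list alone), ATP5PD among them (−1.63 ± 0.28). By camera the adjusted p was 3e-06 and 5.75e-05, and p = 0.677 for either with an estimated correlation. Of 40 cytosolic ribosomal proteins 28 fell (32 adjusted over the list alone), with a median of −0.83 and RPL23 at −1.63 ± 0.29 (camera adjusted p = 6.71e-14, and p = 0.677 with an estimated correlation). Of 13 mitochondrially encoded mRNAs 11 fell (12 adjusted over the list alone), with a median of −2.33 and MT-ND3 at −2.67 ± 0.47, and of 33 mitochondrial ribosomal proteins 14 (15 lower and 2 higher adjusted over the list alone), MRPL22 among them (−1.23 ± 0.24). Camera gave adjusted p of 6.23e-07 and 0.00246, and p = 0.682 for either with an estimated correlation. The ribosomal protein mean was 9.94 log2 CPM in control 1, 9.45 in control 3 and 8.90 to 9.17 in preconditioning libraries. Within the lower-share set the medians were −0.46 for ribosomal proteins, −0.43 for complex I, −0.81 for mitochondrially encoded mRNAs and 1.96 for cholesterol synthesis. These values rest on control 3 as the only control, and in the same fit 16 of 18 heat shock and 15 of 29 ATF4 target genes were lower, so they hold what was particular to that library. The higher-share set held no preconditioning library.

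Of snoRNA host genes 7 of 13 fell and 1 rose (7 and 1 adjusted over the list alone), with SNHG6 (−2.09 ± 0.39) and GAS5 (−1.07 ± 0.23) lower (camera adjusted p = 0.00393, and p = 0.682 with an estimated correlation), and this list call ended without control 3. The largest falls were ANGPTL4 (−4.03 ± 1.01), MT-RNR2 (−3.14 ± 0.78), DRD4 (−3.04 ± 0.65), the chemokine gene CCL2 (−2.99 ± 0.67), MT-TP (−2.95 ± 0.57) and SCX (−2.82 ± 0.39). ANGPTL4 was at 91.3 CPM in control 3 and at 5.05 and 4.31 CPM in control 1 and 2. Of the fixed genes DDIT3 (−1.43 ± 0.42), GDF15 (−1.38 ± 0.34) and the haem oxygenase HMOX1 (−1.70 ± 0.42) fell. HMOX1 was at 271.9 CPM in control 3 and at 49.3 and 63.4 CPM in control 1 and 2. The calls of ANGPTL4 and HMOX1 ended without control 3, that of CCL2 without control 2, and that of DDIT3 without control 1, control 2, preconditioning 1, preconditioning 2 or preconditioning 3. Of 49 called genes taken by the rule 42 held their call without each library in turn.

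In all, 3950 genes were called by edgeR, 1765 higher and 2185 lower, and 9 of 47 lists passed by camera, none of them with an estimated correlation. Library totals as the only scaling shifted the median of all genes by 0.12 and made 55.2% of calls higher, against 44.7%, and taking out the length and GC trend made 30.2% higher. The count was 459 with the library set as a term, 436 of them among the 3950 in the same direction. Within the lower-share set control 3 was the only control, so no count is given there. The count was 1506 without control 1, 1911 without control 2 and 6057 without control 3. It was 2300 without preconditioning 1, 2406 without preconditioning 2 and 8405 without control 3, FCCP 1 and preconditioning+FCCP 3. The mitochondrial share of counts averaged 1.46% ± 0.35 (SD, n = 4) with preconditioning and 7.18% ± 3.63 (SD, n = 3) in control, with an exact two-sided permutation p of 0.0286, the smallest these libraries allow, and 0.114 after adjustment over 4 comparisons. It was 3.00% in control 3. FCCP libraries averaged 3.33% ± 2.75 (SD, n = 3), with an exact permutation p of 0.20 against control, where 0.10 is the smallest possible, and 0.267 after adjustment.

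**Figure D2:**
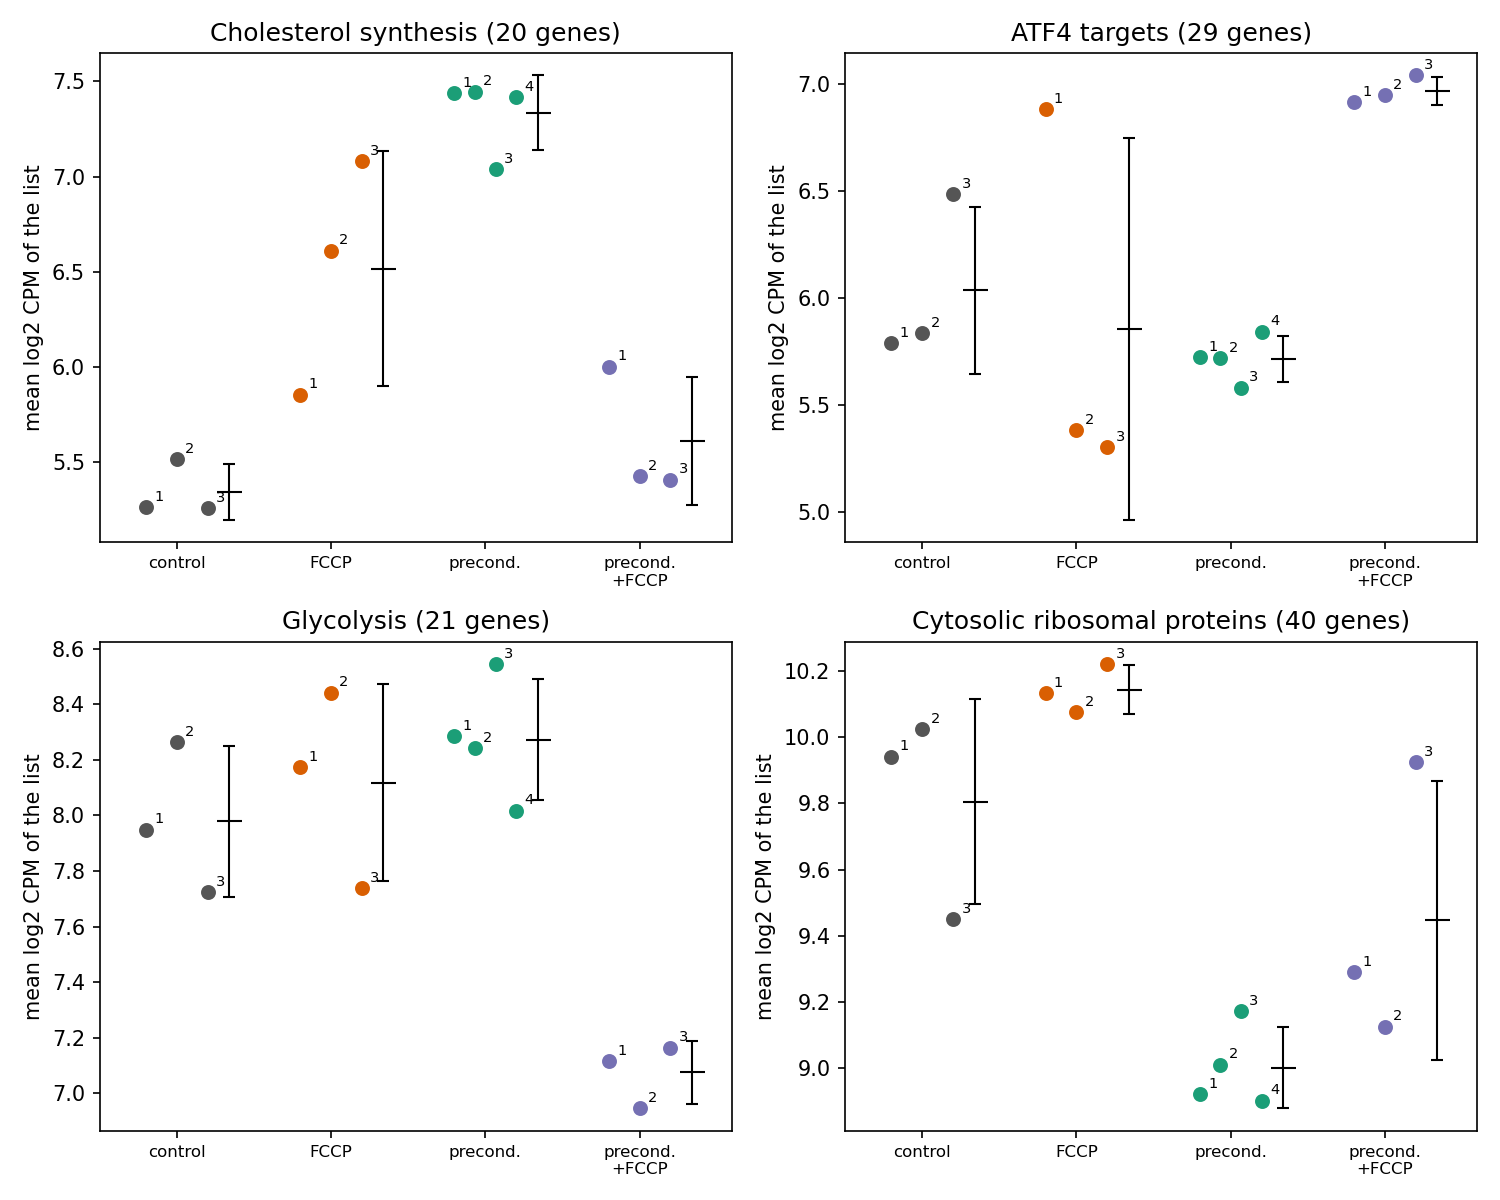
Each point is the mean log2 CPM of a gene list in a library, numbers name replicates, and bars give the group mean ± SD. Cholesterol synthesis lies at 7.04 to 7.45 in preconditioning and at 5.41 to 6.00 in preconditioning+FCCP libraries, ATF4 targets at 6.88 in FCCP 1 and at 5.38 and 5.30 in FCCP 2 and 3, and ribosomal proteins follow the library sets.

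The comparison of preconditioning+FCCP with FCCP asked what preconditioning changed under FCCP. Collagens and other fibroblast markers fell, with 11 of 14 lower and 1 higher (11 and 1 adjusted over the list alone), among them COL1A1 (−2.72 ± 0.28), COL3A1 (−3.35 ± 0.47) and THY1 (−1.72 ± 0.23), with camera adjusted p = 1.52e-05, and p = 0.499 with an estimated correlation. Of 25 extracellular matrix genes 12 fell and 1 rose (12 and 1 adjusted over the list alone), COL5A1 lower (−1.58 ± 0.19), with camera adjusted p = 3.1e-05, and p = 0.297 with an estimated correlation. Glycolysis genes fell in 15 of 21 cases (16 adjusted over the list alone), with the lactate dehydrogenase LDHA (−2.67 ± 0.40), the lactate exporter SLC16A3 (−2.31 ± 0.29) and ENO1 (−1.51 ± 0.25) lower (camera adjusted p = 2.58e-06, and p = 0.591 with an estimated correlation). Cholesterol synthesis was lower in 13 of 20 cases (13 adjusted over the list alone), with LSS (−1.60 ± 0.26) and DHCR7 (−2.06 ± 0.38), and fatty acid synthesis in 5 of 12 (5 adjusted over the list alone), with SREBF1 (−1.68 ± 0.26). Their camera adjusted p was 0.000259 and 0.0078, and p = 0.591 and 0.604 with an estimated correlation.

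Targets of ATF4, the transcription factor of the integrated stress response, were higher in 11 of 29 cases and lower in 1 (11 and 1 adjusted over the list alone), with VLDLR (1.47 ± 0.31) and ALDH1L2 (1.41 ± 0.31) up and PYCR1 (−1.04 ± 0.22) down (camera adjusted p = 4.71e-05, and p = 0.591 with an estimated correlation). FCCP 1 had a list mean of 6.88 log2 CPM, near the 6.91 to 7.04 of preconditioning+FCCP. Of 18 genes of the unfolded protein response of the endoplasmic reticulum 8 rose (8 adjusted over the list alone; SYVN1 1.09 ± 0.19), and of 20 tRNA synthetases 7 rose and 1 fell (7 and 1 adjusted over the list alone; IARS1 1.14 ± 0.27 up). By camera the adjusted p was 0.0105 and 0.0447, and p = 0.684 and 0.734 with an estimated correlation. Of 19 p53 targets 12 rose and 2 fell (12 and 2 adjusted over the list alone), with the death receptor gene TNFRSF10B (1.77 ± 0.33) up and the pro-apoptotic BAX (−1.19 ± 0.20) and FDXR (−1.04 ± 0.19) down. Immediate early genes rose in 9 of 22 cases (10 adjusted over the list alone), with EGR2 (3.00 ± 0.55) and FOSB (3.51 ± 0.68). Antioxidant enzymes fell in 7 of 17 cases and rose in 1 (8 and 1 adjusted over the list alone), with PRDX2 (−1.42 ± 0.19) and PRDX5 (−1.26 ± 0.19) lower. These lists had camera adjusted p of 0.00845, 0.00666 and 0.00666, and p = 0.591 for each with an estimated correlation.

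Ribosomal proteins fell in 20 of 40 cases (25 adjusted over the list alone; RPS3 −0.89 ± 0.20), complex I in 15 of 37 (15 lower and 1 higher adjusted over the list alone; NDUFS8 −1.07 ± 0.21), complexes II to IV in 12 of 23 (16 adjusted over the list alone; COX6B1 −1.46 ± 0.30) and ATP synthase in 12 of 16 (14 adjusted over the list alone; ATP5MC1 −1.20 ± 0.20). Camera gave adjusted p of 1.65e-08, 0.000158, 1.52e-05 and 1.52e-05, and p = 0.591 for each with an estimated correlation. The ribosomal protein mean was 9.92 log2 CPM in preconditioning+FCCP 3, of the higher-share set, and 9.29 in preconditioning+FCCP 1, of the lower-share set. The largest rises were COL20A1 (3.33 ± 0.77), QRICH2 (3.27 ± 0.77), NGFR (3.11 ± 0.76), EGR2, BICDL1 (2.93 ± 0.48) and TRAPPC6B (2.77 ± 0.48). The largest falls were ZP1 (−4.98 ± 0.98), COLEC12 (−4.80 ± 0.88), ELANE (−4.77 ± 0.90), OLR1 (−4.57 ± 0.78), GPR78 (−4.27 ± 0.73) and CLIC3 (−3.93 ± 0.60). ZP1 and ELANE rested on 14 and 15 counts in all preconditioning+FCCP libraries together. Of the fixed genes DDIT3 (1.27 ± 0.44), TRIB3 (1.87 ± 0.59) and SQSTM1 (1.79 ± 0.45) rose and TXNIP (−1.65 ± 0.51) fell.

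In all, 5976 genes were called by edgeR, 3007 higher and 2969 lower, and 15 of 47 lists passed by camera, none of them with an estimated correlation. Library totals as the only scaling shifted the median of all genes by 0.18 and made 64.1% of calls higher, against 50.3%. The count was 3629 with the library set as a term, 9276 without control 3, FCCP 1 and preconditioning+FCCP 3, 3964 without FCCP 2, 3848 without FCCP 3 and 3910 without preconditioning+FCCP 2. Within the higher-share set preconditioning+FCCP 3 stood alone against 3 FCCP libraries and the spread came from the FCCP and control libraries, so the 3 genes called there say little about the group. The medians there were −1.49 for fibroblast markers, −1.07 for glycolysis, −1.36 for cholesterol synthesis, 0.92 for ATF4 targets and −0.21 for ribosomal proteins, and the lower-share set held no FCCP library. Of 72 called genes taken by the rule 63 held their call without each library in turn. The call of DDIT3 ended without FCCP 2, FCCP 3 or any preconditioning+FCCP library, that of TRIB3 without any of these but preconditioning+FCCP 3, and that of TXNIP without any but preconditioning+FCCP 2. The list call of tRNA synthetases ended without FCCP 2, FCCP 3, preconditioning+FCCP 1 or preconditioning+FCCP 3, and with the library set as a term it ended with those of the unfolded protein response, antioxidant enzymes and complex I. The mitochondrial share averaged 3.36% ± 2.70 (SD, n = 3), with an exact permutation p of 1.0 against FCCP.

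The comparison of preconditioning+FCCP with preconditioning asked what FCCP did to preconditioned cells. Lipid synthesis was lower, with 18 of 20 cholesterol genes (18 adjusted over the list alone), FDPS (−1.75 ± 0.25) among them, and 10 of 12 fatty acid synthesis genes (11 adjusted over the list alone), ACLY (−1.68 ± 0.17) and FADS2 (−3.43 ± 0.45) among them. Their camera adjusted p was 1.8e-08 and 3.8e-07, and p = 0.333 for either with an estimated correlation. Glycolysis fell in 17 of 21 cases (17 adjusted over the list alone), with SLC16A3 (−2.70 ± 0.28), HK1 (−1.45 ± 0.20) and LDHA (−2.57 ± 0.39), and camera adjusted p = 1.67e-07, and p = 0.333 with an estimated correlation. Extracellular matrix fell in 18 of 25 cases (19 adjusted over the list alone), with COL1A1 (−2.59 ± 0.27) and FBN1 (−1.40 ± 0.20), and camera adjusted p = 3.8e-07, and p = 0.0903 with an estimated correlation. COL1A1 stood at 3384 to 3940 CPM in preconditioning and at 536.3 to 712.8 CPM in preconditioning+FCCP libraries.

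Fibroblast markers fell in 11 of 14 cases (11 adjusted over the list alone; PDGFRB −1.33 ± 0.19), TGF-beta and YAP targets in 12 of 18 with 2 higher (13 and 3 adjusted over the list alone; CRIM1 −1.66 ± 0.19, F3 −2.37 ± 0.29) and smooth muscle markers in 4 of 10 (4 adjusted over the list alone; CALD1 −1.32 ± 0.18). By camera the adjusted p was 2.45e-05, 0.000453 and 0.0469, and p = 0.333 for each with an estimated correlation. ATF4 targets rose in 18 of 29 cases and fell in 1 (19 and 1 adjusted over the list alone), with DDIT3 (3.52 ± 0.43), ATF3 (3.28 ± 0.46) and the cystathionine lyase CTH (2.41 ± 0.36), and camera adjusted p = 5.37e-06, and p = 0.593 with an estimated correlation. Pro-apoptotic factors rose in 11 of 21 cases and fell in 1 (11 and 1 adjusted over the list alone), with BCL2L11 (2.37 ± 0.37) and BBC3 (1.29 ± 0.25) up and CASP8 (−0.75 ± 0.20) down, and camera adjusted p = 0.0232, and p = 0.333 with an estimated correlation. The unfolded protein response rose in 8 of 18 cases (8 adjusted over the list alone; DNAJB9 1.76 ± 0.27), snoRNA hosts in 11 of 13 with 1 lower (11 and 1 adjusted over the list alone; GAS5 1.64 ± 0.23) and histones in 5 of 11 (8 adjusted over the list alone; H2BC21 2.66 ± 0.40). Camera gave adjusted p of 0.00629, 8.86e-05 and 0.00921, and p = 0.709, 0.583 and 0.593 with an estimated correlation. Ribosomal proteins rose in 19 of 40 cases (19 adjusted over the list alone; RPS28 0.69 ± 0.18) and complex I in 9 of 37 with 2 lower (9 and 1 adjusted over the list alone; NDUFV3 0.90 ± 0.16 up, NDUFS1 −0.72 ± 0.15 down). Their camera adjusted p was 0.000258 and 0.0129, and p = 0.793 for either with an estimated correlation, and the calls of these 2 lists and of RPS28 ended without preconditioning+FCCP 3. The smooth muscle list call ended without preconditioning+FCCP 3 and without preconditioning 4, and both it and that of complex I ended with the library set as a term.

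The largest rises were the immediate early genes FOSB (7.01 ± 0.72) and FOS (6.05 ± 0.80), HES1 (4.67 ± 0.79), NGFR (4.67 ± 0.73), DLL4 (5.47 ± 0.85, with 8 counts in all preconditioning libraries together) and COL20A1, which had 4 counts in all preconditioning libraries together and stood at 4.07 to 8.80 CPM with FCCP. The largest falls were the interleukin gene IL1B (−4.87 ± 0.79), RGS4 (−4.69 ± 0.41), LINC02984 (−4.67 ± 0.53, with 13 counts in all preconditioning+FCCP libraries together), COLEC12 (−4.47 ± 0.86), IL7R (−4.41 ± 0.46) and DKK1 (−4.30 ± 0.72). Of the fixed genes TRIB3 (1.97 ± 0.54), CHAC1 (2.41 ± 0.91), ASNS (2.55 ± 0.90) and HMOX1 (1.33 ± 0.42) also rose and TXNIP fell (−1.77 ± 0.49), and the mitochondrial chaperone HSPD1 (−0.02 ± 0.32) and protease LONP1 (0.00 ± 0.18) did not pass. The call of CHAC1 ended without any of the 7 libraries, that of ASNS without any but preconditioning 4, and that of HMOX1 without preconditioning+FCCP 2 or 3.

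In all, 6594 genes were called by edgeR, 3383 higher and 3211 lower, and 14 of 47 lists passed by camera, none of them with an estimated correlation. With library totals as the only scaling 59.1% of calls were higher, against 51.3%. Within the lower-share set (2 preconditioning+FCCP and 4 preconditioning libraries) 9097 genes were called, of which 6407 were among the 6594 with the same direction. The medians there were −1.43 for cholesterol synthesis, −1.29 for glycolysis, −1.50 for fibroblast markers, 1.17 for ATF4 targets and 0.25 for ribosomal proteins. The higher-share set held no preconditioning library. Of 71 called genes taken by the rule 62 held their call without each library in turn. The mitochondrial share had an exact permutation p of 0.114, and 0.229 after adjustment.

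**Figure D3:**
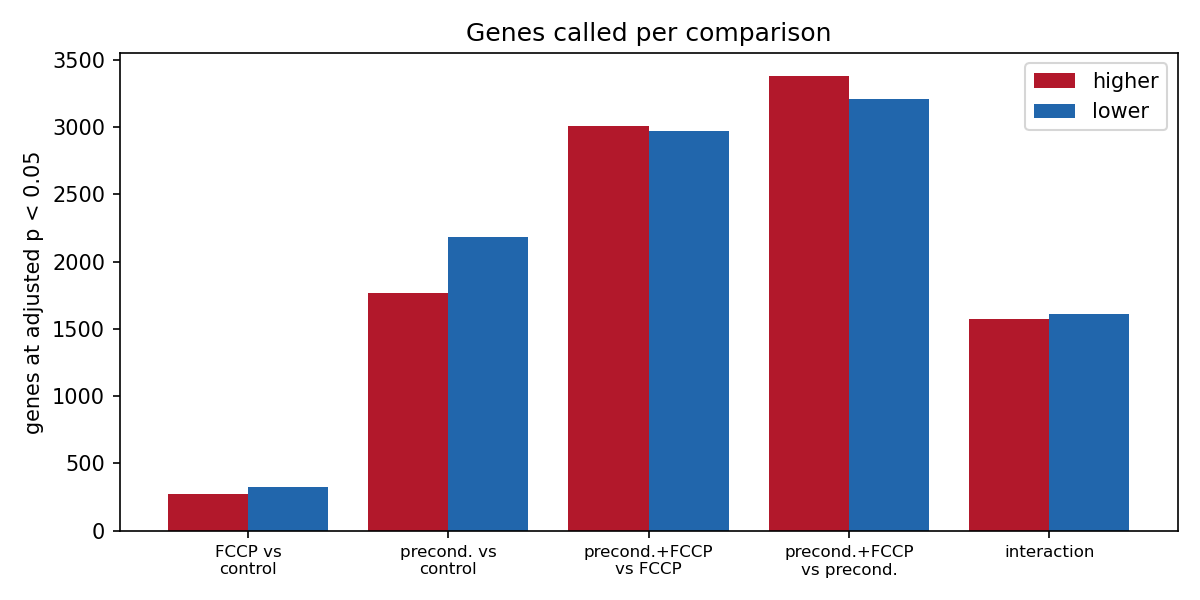
Bars give the number of genes called higher and lower at an adjusted p under 0.05 in each comparison, out of 16756 tested. FCCP against control called 590 genes and preconditioning+FCCP against preconditioning 6594.

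The interaction asked whether the FCCP effect differed with preconditioning. Lipid synthesis was higher after FCCP without preconditioning and lower after FCCP with it, and 19 of 20 cholesterol genes (19 adjusted over the list alone) and 11 of 12 fatty acid synthesis genes (12 adjusted over the list alone) had negative interactions, with medians of −2.72 and −1.86. By camera the adjusted p was 6.5e-18 and 4.58e-11, and p = 0.173 for either with an estimated correlation. INSIG1 (−6.01 ± 0.86), FADS2 (−5.48 ± 0.63), SCD (−5.15 ± 0.87), HMGCS1 (−4.87 ± 0.58) and FASN (−4.67 ± 0.62) were among the 6 most negative genes. Glycolysis was negative in 14 of 21 cases (16 adjusted over the list alone; SLC16A3 −3.02 ± 0.39), with camera adjusted p = 6.93e-09, and p = 0.358 with an estimated correlation. Fibroblast markers were negative in 9 of 14 cases (9 adjusted over the list alone; COL1A1 −2.59 ± 0.36), extracellular matrix in 10 of 25 (10 negative and 1 positive adjusted over the list alone; COL3A1 −3.54 ± 0.62) and smooth muscle markers in 3 of 10 (4 adjusted over the list alone; CALD1 −1.53 ± 0.25). Camera gave adjusted p of 9.55e-06, 2.05e-05 and 0.00874, and p = 0.193, 0.173 and 0.173 with an estimated correlation. The tricarboxylic acid cycle was negative in 6 of 20 cases (7 adjusted over the list alone; SUCLG2 −2.10 ± 0.32), with camera adjusted p = 0.035, and p = 0.518 with an estimated correlation. That list call ended without control 1, FCCP 1, preconditioning 3 or preconditioning+FCCP 2.

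ATF4 targets had positive interactions in 11 of 29 cases and a negative one in 1 (17 and 1 adjusted over the list alone; PSAT1 2.26 ± 0.45, DDIT3 2.70 ± 0.60), with camera adjusted p = 7.71e-07, and p = 0.661 with an estimated correlation. Immediate early genes were positive in 6 of 22 cases (7 adjusted over the list alone; IER2 2.84 ± 0.65), snoRNA hosts in 6 of 13 with 1 negative (10 and 1 adjusted over the list alone; GAS5 1.54 ± 0.34) and mitochondrially encoded mRNAs in 2 of 13 (2 adjusted over the list alone; MT-ND1 3.09 ± 0.87). Their camera adjusted p was 0.0204, 0.0156 and 0.00874, and p = 0.836 for each with an estimated correlation. The list calls of snoRNA hosts and mitochondrially encoded mRNAs ended without preconditioning+FCCP 3, and that of immediate early genes without control 3 or preconditioning+FCCP 2. MT-ND1 lost its call without control 2, FCCP 2, FCCP 3 or preconditioning+FCCP 3. In all, 3180 genes were called by edgeR, 1571 positive and 1609 negative, and 11 of 47 lists passed by camera, none of them with an estimated correlation. With library totals as the only scaling 56.8% of calls were positive, and 55.4% with the length and GC trend taken out, against 49.4%. The count was 2086 without FCCP 2, 2076 without FCCP 3, 2013 without preconditioning+FCCP 2 and 6421 without control 3, FCCP 1 and preconditioning+FCCP 3. Neither library set held all 4 groups, so no within-set value could be had. The share of libraries in the higher-share set has an interaction contrast of 0, so an equal shift of all libraries of a set would cancel. With the library set as a term 4504 genes were called, among them the 3180 in the same direction.

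Across the 6873 genes called in either comparison, the FCCP effects with and without preconditioning had a Pearson r of 0.32, where genes are not independent replicates. Of the 268 genes that FCCP raised without preconditioning 92 also rose with it, against 54.1 for independent lists, and of the 322 lowered genes 132 also fell, against 61.7. Of the 590 genes 87 were called in the opposite direction. The r of 0.32 became 0.042 without FCCP 1. The preconditioning effects with and without FCCP had r = 0.25 over 8417 genes, and −0.099 with the library set as a term. FCCP against control and preconditioning+FCCP against FCCP share the FCCP libraries, and r was −0.35 over all genes, against −0.51 in simulated groups without any effect. The covariance was −0.253, against a simulated −0.102. Of the 590 genes changed by FCCP, 78.8% had the opposite sign in the other comparison, against a simulated 90.3%. By r and by sign the shared libraries alone gave more opposition than was seen. The simulated groups held no real effects, which in the data change r and which genes are called. Neither measure can therefore decide whether preconditioning reversed FCCP changes. The covariance was further from 0 than simulated (SD 0.0025 over 20 simulations), in the direction of opposition. Simulated genes varied independently, so this SD leaves out shifts that many genes of a library share. Of the 590 genes 5 were called higher and 15 lower in both comparisons and 294 were called in opposite directions, counts that the shared libraries also move.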

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

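The tests of the library set, of gene length and GC content and of FCCP 1 in this part were chosen after results were seen, and only for length and GC content was the expected outcome written before the test was run, while the count over other splits of the libraries did not depend on any result.

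In 14 of 219 values tested over the 4 preconditioning libraries, 1 library stood apart, by a gap to the nearest other library that passed Dixon's critical value. Chance gives this in about 1 of 20 groups, which is close to the share seen. The values are not independent, as the cholesterol synthesis mean holds HMGCS1, DHCR7 and INSIG1. Preconditioning 3 was that library in 12 cases. Its log2 CPM was lower than in the others for HMGCS1 (gap 0.945 of the range), DHCR7 (0.887), INSIG1 (0.868), FADS1 (0.837), the cholesterol synthesis mean (0.93), ALDH1L2 (0.892) and MT-TP (0.877). It was higher for HMOX1 (0.985), UQCR11 (0.876), CYC1 (0.847), OGDH (0.847) and UQCRC1 (0.839). ATP5PO was higher in preconditioning 2 (0.869) and IL7R lower in preconditioning 4 (0.841).

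The effect of FCCP differed between cells with and without preconditioning, by the edgeR interaction, in 3180 genes. The largest positive log2 differences were ANGPTL4 (5.36), COL20A1 (5.31), QRICH2 (4.71), FOS (4.03), MT-RNR1 (3.89) and FOSB (3.69). The most negative were INSIG1 (−6.01), FADS2 (−5.48), SCD (−5.15), HMGCS1 (−4.87), LINC02984 (−4.72) and FASN (−4.67). The call of ANGPTL4 ended without control 3 or FCCP 2, and that of FOS without control 2. By camera the lists that differed had medians of 1.38 for ATF4 targets, 1.92 for mitochondrially encoded mRNAs, 1.07 for immediate early genes, 1.22 for snoRNA hosts, −0.39 for the tricarboxylic acid cycle, −1.41 for glycolysis, −2.72 for cholesterol synthesis, −1.86 for fatty acid synthesis, −0.62 for extracellular matrix, −1.53 for fibroblast markers and −1.25 for smooth muscle markers, none of them called with an estimated correlation.

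Ribosomal protein and respiratory chain genes were lower in preconditioning than in control, with a median log2 change of −0.85 over 100 genes. Taking out the trend on gene length and GC content left 90.5% of it (SE 10.1), which argues against that trend as the whole cause. This SE and the next come from the spread between the genes, which are not independent. They leave out the spread between libraries. With the library set as a term, which rests on the control and preconditioning+FCCP libraries as the only groups in both sets, the median was −0.43, with 11 genes called in place of 65, and 50.6% of the change was left (SE 4.7), close to the bound of 50%, while the camera call stayed (unadjusted p = 1.3e-17 with the preset correlation). By the rule as first written this would argue against the library set, but that the bound must be passed by more than the SE was added after this value was seen. All 4 preconditioning libraries lie in the lower-share set, so the library set and preconditioning cannot be told apart for these genes. The set was also defined by reads aligned to several places, to which ribosomal protein genes may add through their pseudogenes. The ribosomal protein mean was 9.92 to 10.22 log2 CPM in higher-share and 8.90 to 9.45 in lower-share libraries. The set may thus hold part of the change it was used to test, so the 50.6% cannot decide the question. An effect of preconditioning stays open.

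Cholesterol synthesis genes were higher in preconditioning than in control and lower in preconditioning+FCCP than in preconditioning, comparisons that share the preconditioning libraries. With the library set as a term 97.3% and 91.4% of the medians were left, and with the length and GC trend taken out 85.1% and 91.6%, which argues against either as the whole cause. Other technical differences were not tested, and whether control cells carried the construct or received light is not known. Under these limits, a candidate explanation is that preconditioning, or the construct or light that came with it, raised this pathway and FCCP lowered it in preconditioned cells alone, since without preconditioning FCCP raised it (median 1.28), as a hypothesis found and tested on the same data.

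ATF4 targets were higher in FCCP 1 than in FCCP 2 and 3. An exchange with a preconditioning+FCCP library would need a library of that group nearer to FCCP 2 or 3, but each correlated better with its own group, by at least 0.036. A preconditioning+FCCP library with a wrong label would share that group's low glycolysis mean of 7.08 ± 0.115 log2 CPM (SD, n = 3), but FCCP 1 was at 8.17, which is 9.6 SD away. A different strength of the FCCP exposure could give such a difference and was not tested.

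Other splits of the libraries bear on the counts of called genes. For preconditioning against control 1 of 35 splits, the real one, called 3950 genes and the others at most 0. For preconditioning+FCCP against preconditioning 1 of 35 called 6594 and the others at most 1. This is the smallest share that 35 splits allow, without adjustment over the comparisons, so chance is made less likely but not excluded. Nor can these splits tell preconditioning from the library set, as all preconditioning libraries lie in the lower-share set. For FCCP against control, 10 splits are too few for a share under 0.05, with 590 genes for the real split and at most 4 for the others, and likewise for preconditioning+FCCP against FCCP, with 5976 and at most 1. For the interaction, 2 of 100 splits called at least 3180 genes, but these splits also break the effect of preconditioning itself, so they do not test the interaction alone. The other of these splits called 5233, with all FCCP and preconditioning+FCCP labels exchanged and control 3 exchanged with preconditioning 3. The first exchange turns the contrast into the effect of preconditioning over cells with and without FCCP, so this count says nothing about the interaction.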

How the results depend on the processing

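The tests without control 3, FCCP 1 and preconditioning+FCCP 3, with the library set as a term, within each set, and with the length and GC trend taken out were chosen after the data were seen. The 3 libraries were picked because they stood apart, which by itself narrows the spread. DESeq2 size factors, library totals, mitochondrial genes left out, a filter of 1 CPM in 3 libraries and the length and GC trend each kept all 5 counts of called genes within 1.5 times. The genes behind the counts changed more. Of the 590 genes of FCCP against control, 335 kept their call with the trend taken out and 370 under library totals. With DESeq2 size factors 551 did, without mitochondrial genes 588 and with that filter 582. Of the 3950 genes of preconditioning against control, 2529 kept theirs with the trend taken out and 3357 under library totals. Under library totals all 61 list calls kept their side of the threshold, and with an estimated correlation none of 61 did. Of the 61, 18 ended by fry, 13 with the library set as a term, 9 without the 3 libraries, 7 with the length and GC trend taken out and 1 with DESeq2 size factors. Of 315 named-gene values, 40 weakened with the set as a term. Genes changed 2-fold were recovered in 20% of simulated cases for FCCP against control and in 3% for the interaction, which limits what a missing call shows.

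For FCCP against control (590 genes called) the count was 23 at an adjusted p under 0.01 by edgeR, 1078 without a filter, 1326 by DESeq2, 382 by limma-voom, 191 against a 1.2-fold change, 17 with the compared groups alone, 3113 without the 3 libraries, 938 with the library set as a term, 31 within the higher-share set, and 142 (without FCCP 2) to 893 (without FCCP 1) with 1 library left out. For preconditioning against control (3950) it was 1424 at the stricter threshold, 2548 against a 1.2-fold change, 8405 without the 3 libraries, 459 with the set as a term, and 1506 (without control 1) to 6057 (without control 3). For preconditioning+FCCP against FCCP (5976) it was 3161 at the stricter threshold, 9276 without the 3 libraries, 3629 with the set as a term, 3 within the higher-share set, and 3848 (without FCCP 3) to 6943 (without FCCP 1). For preconditioning+FCCP against preconditioning (6594) only the stricter threshold moved it, to 4022. For the interaction (3180) it was 1201 at the stricter threshold, 6421 without the 3 libraries, and 2013 (without preconditioning+FCCP 2) to 4576 (without FCCP 1). A stricter threshold or a fold to pass lowers a count by construction, and otherwise the cause was not tested, for rises with fewer libraries as well.

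Replicate numbers showed no clear pairing of the libraries. Of 18 pairs with the same number 1 had deviations that correlated above 0.1 (range −0.2 to 0.158), and 2 of 13 libraries correlated best with their own number. Deviations from the means of such small groups cannot exclude a pairing. With a replicate block the counts were 53 for FCCP against control, 1840 for preconditioning against control and 1897 for the interaction, and the others stayed within 1.5 times, while 43 named-gene values and 1 list call weakened.

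CHAC1 in FCCP against control went from 0.05 to −3.10 without the 3 libraries, and with 1 library left out ran from −3.97 (without FCCP 1) to 0.933 (without control 3). TRIB3 in preconditioning against control went from −0.17 to 0.547 without the 3 libraries. The correlation of the FCCP effects with and without preconditioning (0.32) was 0.227 over all genes, 0.042 without the 3 libraries, and 0.042 (without FCCP 1) to 0.438 (without FCCP 3). That of the preconditioning effects (0.25) was 0.392 without the 3 libraries, −0.099 with the set as a term, and 0.14 (without preconditioning+FCCP 1) to 0.355 (without preconditioning+FCCP 3). That of the FCCP and the preconditioning+FCCP against FCCP changes (−0.54 over 590 genes) was −0.345 over all genes and −0.747 (without FCCP 1) to −0.305 (without control 3). The cause was not tested.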

Other observations

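The values in this part were taken from the tables after the results were seen, and no further test was made for it. Heat shock proteins separated control 3 from its group. The mean of 18 cytosolic heat shock genes was 8.74 log2 CPM in control 3, against 7.19 and 7.17 in control 1 and 2, and 7.21 to 7.53 in preconditioning libraries. HSPA1A, the inducible HSP70, chosen after its values were seen, was at 697.1 CPM in control 3 and at 135.8 and 80.3 CPM in control 1 and 2. Among FCCP libraries HSPA1A was at 36.9 CPM in FCCP 1 and at 700.3 and 508.3 CPM in FCCP 2 and 3. The list was not called in any comparison. Whether the label of control 3 is right was not tested. That of preconditioning+FCCP 3 was tested only for an exchange with FCCP 1, by its correlations with its own group and with FCCP 2 and 3. It correlated at 0.959 and 0.972 with preconditioning+FCCP 1 and 2, at 0.923 and 0.917 with FCCP 2 and 3, and at 0.965 with FCCP 1. The cholesterol synthesis mean of control 3 was 5.26 log2 CPM, against 5.26 and 5.51 in control 1 and 2 and 7.04 to 7.45 in preconditioning libraries.

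Interferon-stimulated genes varied within groups, with means of 2.70 to 4.71 log2 CPM in preconditioning+FCCP and 3.69 to 5.02 in preconditioning libraries. In preconditioning+FCCP against preconditioning 10 of 25 were lower and 3 higher (10 and 3 adjusted over the list alone), with camera adjusted p = 0.0803, so the list did not pass. Metallothioneins were higher in 4 of 7 cases there (4 adjusted over the list alone), with camera adjusted p = 0.128. FCCP and preconditioning, each against the same control libraries, had r = 0.10 over all genes, against 0.54 in simulated groups without effect, with a covariance of 0.058 against 0.099.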
